A study of Mus musculus with 25 samples.

How the data were processed

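Single-cell RNA libraries (10x Chromium v3) were measured from unsorted cells of mouse marrow, blood, lung, spleen and mammary tumor, 25 libraries in 16 groups. Red cells were lysed in each tissue, and lung and tumor were dissociated with an enzyme kit, per the labels. The deposited values are UMI counts per gene and barcode, which the authors made with Cell Ranger 6.0.2 and STAR 2.7.10b on GRCm38; the file headers name cellranger-6.0.0 and the gene annotation version is not stated. The deposited barcode lists hold a round number of barcodes per library (9000 to 30000), some with as few as 16 UMIs, so cells were filtered again here. The 52553 features include the transgenes PyMT and Cre. Groups, replicate numbers and batches (8) came from the sample labels; nothing in the labels says whether libraries of a group came from separate animals.

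Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, and the barcodes with the highest doublet scores (scrublet, within scanpy 1.11.5) were removed at 0.8% per 1000 cells. Each library was clustered on its own (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, seed 1; leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, Python 3.11.15). The 711 clusters were named from fixed marker lists of 16 cell classes, with at least 3 markers needed. The marker lists were fixed beforehand but the scoring rule was not. It went through at least 4 versions with the clusters in view: a z score over all clusters, a background taken within each library, a floor of 3 on the scale of each class after eosinophil scores won too often, and a stricter check of neutrophil clusters against markers of other classes. Neutrophil shares had been seen when the floor and the stricter check were set, and no gene had been tested. Earlier versions were not carried through the comparisons, so how far the neutrophil shares depend on that choice is known only from the marker-picked cells and from adding unnamed clusters. In the last version 175 were named neutrophil or granulocyte progenitor and 59 stayed unnamed, 14 of them with a neutrophil or progenitor best score. These 14 held on average 2.27% of cells in wildtype marrow, 2.86% in PyMT marrow, 0.41% with vehicle, 2.88% with G-CSF (0% to 5.76%), 1.70% with E0771, 6.16% in uninjected marrow, 0.58% with IgG and 0.68% with the antibody, and 0% in other tissues.

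UMI counts of cells named neutrophil or granulocyte progenitor were summed per library. The 18 libraries of the 9 groups with 2 libraries were fitted together with the edgeR 4.0.16 quasi-likelihood F test (TMM scaling, filterByExpr, 17401 genes, 9 residual degrees of freedom, Benjamini-Hochberg at 0.05; R 4.3.3, limma 3.58.1). Gene lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated, over 34 lists (20 of neutrophil programmes and 14 of other cell types). Neutrophil shares were compared by exact permutation. Groups with 1 library had no test: log2 ratios used a pseudocount of 5 CPM, and the median of a list was ranked among 10000 random lists matched on mean expression in 20 bins. Random lists do not keep the correlation between genes of a list, so these ranks may overstate how unusual a list of co-regulated genes is. Groups, tests, gene lists, marker lists and alternatives were chosen before the data were examined, apart from the cluster scoring rule and the tests and alternatives named as later in the closing section.

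Genes were named by a fixed rule: up to 12 higher and 12 lower genes with the largest fold change among those past the threshold, moved the same way in both same-batch pairs and with a mean of at least 30 CPM in the higher group, and up to 4 members of each list with the smallest p. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, sex-linked and clone-named genes and markers of other cell types were left out. For single libraries up to 10 genes per direction with at least 50 CPM in the higher library were taken. The report names a part of the genes so taken. For genes taken by fold change, agreement of the pairs was set by this rule and adds no support. A fold against a group at 0 is a lower bound from a floor of 3 counts over the group, and intervals of UMI ratios and of CPM cover counting error alone, as those of cell shares cover the sampling of cells.

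The labels give each library a batch, which pairs the replicates of compared groups, and pairing was checked: over 6497 genes with a mean of at least 10 CPM, deviations of same-batch libraries from their group means had a correlation of 0.49 for PyMT and wildtype marrow, 0.39 for blood, 0.46 for lung, 0.42 for G-CSF and vehicle and -0.13 for tumor and lung. The comparisons were therefore repeated with the labelled batch as a block, called the replicate block (5 residual degrees of freedom). Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 13.9 to 754 for genes of at least 20 counts. Log2 CPM of the 2 replicates had a correlation of 0.863 in tumor to 0.990 with G-CSF. Neutrophil sums in the fit ran from 505558 to 107991783 UMIs and the common dispersion was 0.0912. The tests were tested on simulated data, where changed genes had a mean of at least 10 CPM and as many rose as fell. Simulated counts were independent, with no batch effect and no other difference between groups. The real libraries share deviations within a batch, so the rates below may not carry over to them. With 100 genes changed 4-fold, edgeR recovered 93% in PyMT marrow, 87% in blood, 91% in lung, 96% with G-CSF and 64% in tumor over lung, and at 2-fold 15%, 9%, 10%, 21% and 6%, with 7, 3, 10, 2 and 0 false calls. DESeq2 recovered 95%, 89%, 93%, 100% and 66% at 4-fold with 20, 15, 26, 21 and 12 false calls.

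Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, the replicate block, a fit on the libraries of the comparison alone, a minimum of 1000 UMIs, a mitochondrial limit of 20%, no doublet removal, cells picked one by one by neutrophil markers, mature neutrophil clusters alone, a pseudocount of 1 CPM and each replicate left out in turn, where the lone library of an arm was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9.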

Results

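UMI counts of single cells were measured in 25 droplet libraries of unsorted cells from mouse bone marrow, blood, lung, spleen and mammary tumor. MMTV-PyMT mice carry the polyoma middle T oncogene under a mammary promoter and develop mammary tumors. PyMT and wildtype mice gave 2 libraries per group in marrow, in blood and in lung and 1 per group in spleen, and PyMT tumors gave 2 libraries. Marrow of mice given G-CSF, the cytokine that drives granulocyte production, or vehicle gave 2 libraries per group. Marrow of PyMT mice given control IgG, of PyMT mice given an antibody against G-CSF, of uninjected mice and of mice with E0771, a mouse mammary carcinoma line, gave 1 library per group, as did a PyMT lung sample titled Mets. By the labels 23 of the 25 libraries, those called wildtype and vehicle included, are of a Cre genotype. The uninjected and E0771 marrow libraries are of genotype Naive. The word wildtype follows the library titles. Library totals ran from 28652197 to 211969254 UMIs, and 1121 to 11291 cells per library passed the filters. Cells named neutrophil or granulocyte progenitor, called neutrophils here, numbered 163 and 181 in the 2 tumor libraries and 123 in wildtype spleen, and up to 9468 in a G-CSF marrow library. The PyMT transgene had 41375 and 64704 UMIs in the 2 tumor libraries, of which 40970 and 63531 lay in cells named epithelial, and at most 1 UMI in any wildtype library. In marrow it had 4 and 2 UMIs in PyMT replicates 1 and 2, against 10 in uninjected and 3 in E0771 marrow. Its UMIs therefore do not separate genotypes in marrow.

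Neutrophils took a larger share of the cells of PyMT mice than of wildtype mice in each tissue with both. In marrow the share was 78.8% ± 3.49 (SD, n = 2) with PyMT against 53.3% ± 0.271 in wildtype, in blood 39.7% ± 16.3 against 5.32% ± 4.47, and in lung 50.1% ± 0.134 against 4.93% ± 2.41. The single spleen libraries held 9.17% (95% Clopper-Pearson interval 8.60 to 9.77) with PyMT and 1.34% (1.11 to 1.59) in wildtype. Intervals of shares cover the sampling of cells within a library, not variation between mice. G-CSF took the marrow share to 87.1% ± 1.21 (n = 2), against 62.0% ± 5.28 with vehicle. E0771 marrow held 84.0% neutrophils (83.2 to 84.8) against 58.0% (57.0 to 59.1) in uninjected marrow, and PyMT marrow held 80.5% (79.5 to 81.5) with IgG and 55.6% (54.4 to 56.7) with the antibody against G-CSF. Tumors held 2.80% (2.39 to 3.26) and 2.56% (2.20 to 2.95). Picking cells one by one by markers took several times as many cells in both tumor libraries, so the tumor shares depend on how cells are named. The share was higher with PyMT in 7 of 7 same-tissue, same-batch pairs, by 31.1 percentage points on average (SD 14.0). An exact two-sided sign-flip permutation test gave p = 0.0156, the smallest that its 128 sign patterns allow. A blood and a lung pair shared a labelled batch and may not be independent. With pairs of a batch flipped together p was 0.03125, the smallest of 64 patterns over 6 batches. Within a tissue, 2 libraries against 2 cannot give an exact permutation p under 0.333, so the differences of 25.5 points in marrow, 34.4 in blood, 45.2 in lung and 25.2 with G-CSF stand as values.

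**Figure D1:**
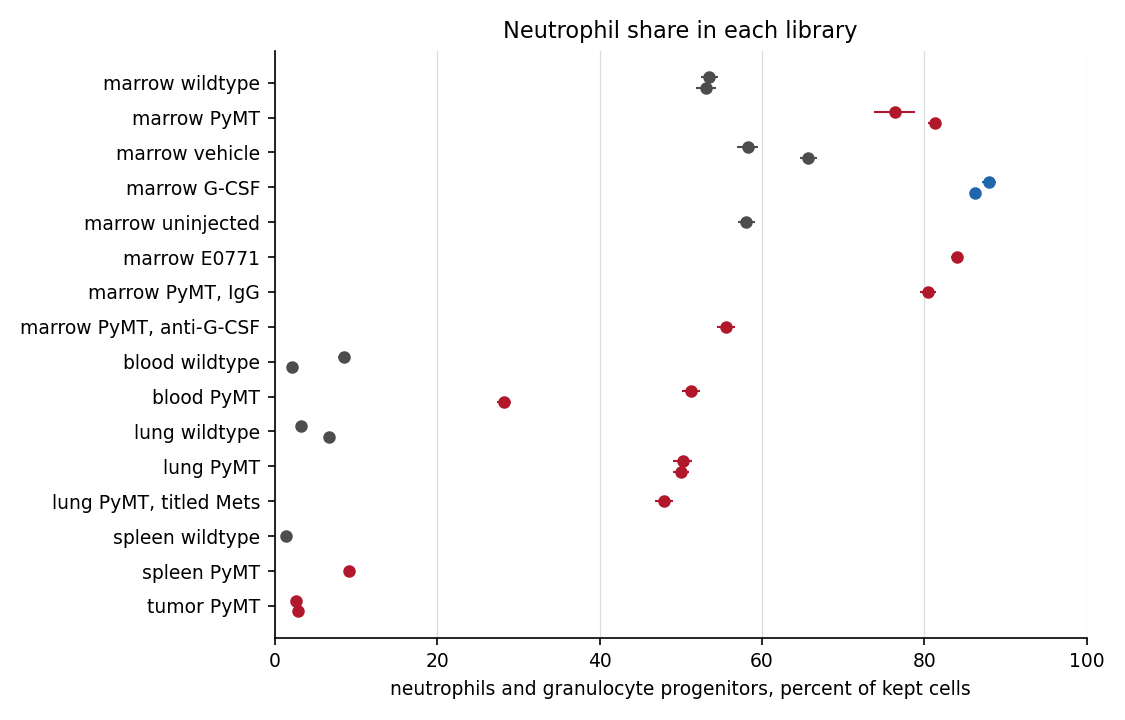
Share of neutrophils and granulocyte progenitors among the kept cells (x axis, percent) for each of the 25 libraries, by group (y axis). Bars are 95% Clopper-Pearson intervals. Both PyMT lung libraries sit at 50.03% and 50.22%, against 6.63% and 3.23% in wildtype lung.

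Marrow of PyMT and wildtype mice was compared to ask what the tumor-bearing state does to neutrophils where they are made. Wfdc17 (ENSMUSG00000069792), a secreted whey acidic protein family member, was 17.8-fold higher in PyMT marrow neutrophils, at 1776 ± 723 CPM (UMI counts scaled to a common library total by TMM; mean ± SD, n = 2) against 100 ± 1.80. Ifitm1 (ENSMUSG00000025491), an interferon-inducible membrane protein, stood at 1366 ± 687 against 124 ± 7.73 CPM, and Prok2 (ENSMUSG00000030069), a secreted chemoattractant peptide, at 263 ± 40.4 against 36.8 ± 12.9 CPM. Igfbp6 (ENSMUSG00000023046), a binding protein of insulin-like growth factors, rose by 4.76 in log2 fold change (SE 0.66). Thbs1 (ENSMUSG00000040152), the matrix glycoprotein thrombospondin 1, fell by 4.74 on the log2 scale (SE 0.61), from 50.3 ± 1.45 to 1.92 ± 0.372 CPM. Further genes that rose were Lipg, an extracellular lipase (4.70, SE 0.75), Steap4, a metalloreductase (3.94, SE 0.53), Fam20c, a kinase of secreted proteins (3.41, SE 0.43), and Npl, an enzyme of sialic acid breakdown (2.64, SE 0.43). Upp1, a uridine phosphorylase, rose by 2.52 (SE 0.55) and Plscr1, a phospholipid scramblase, by 1.57 (SE 0.31). Irf8, a transcription factor of monocyte and dendritic cell fate, fell by 3.86 (SE 0.54). Monocyte and macrophage markers fell in the same sums, so RNA of such cells stays open as a source of that fall. Sntb1 (ENSMUSG00000060429), a cytoskeletal adaptor, fell by 3.34 (SE 0.37) and Fmnl2 (ENSMUSG00000036053), an actin-assembling formin, by 1.86 (SE 0.33). Fmnl2 is among the 100 genes with the largest ratio of immature to mature neutrophils in wildtype marrow, and with mature clusters alone it lost its call (-1.57, adjusted p = 0.212), so a shift in stage stays open for it. Adjusted p of these genes ran from 0.000866 to 0.0441 (edgeR), each in the same direction in 2 of 2 same-batch pairs. With cells picked one by one by markers, 12 of the 20 genes named for this comparison kept their call and 8 did not.

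By gene list, 3 of 31 immunosuppressive and protumour neutrophil genes rose in PyMT marrow (Wfdc17, Ifitm1 and Prok2), 0 fell and 28 did not pass. 5 rose and 0 fell adjusted over the list alone. Their median log2 fold change was 0.49 (0.41 with genes that have a group at 0 at their bound) and the list test (camera) gave adjusted p = 2.09e-07, or adjusted p = 0.279 with an estimated correlation. In the G-CSF and STAT3 signalling list 1 of 20 rose, Socs3, a feedback inhibitor of STAT3 (2.14, SE 0.40), and 4 adjusted over the list alone. The median was 0.22. By camera, adjusted p was 0.000306, or adjusted p = 0.279 with an estimated correlation. No cell cycle gene passed alone (0 of 30), yet 29 of 30 were positive with a median of 0.54, which camera called at adjusted p = 1.71e-07 (0 passed adjusted over the list alone), or adjusted p = 0.304 with an estimated correlation. Granulocyte progenitors were 5.76% and 21.4% of the summed cells in PyMT replicates 1 and 2 and 5.93% and 6.76% in wildtype, and their part in this change was not tested. Scaled by library totals in place of TMM, 22 of 30 were positive with a median of 0.24, where the median of all genes was -0.33. Glycolysis genes had a median of 0.52 (18 of 19 positive, 13 by library totals, 0 passed; camera adjusted p = 8.21e-05, or adjusted p = 0.279 with an estimated correlation). In both pairs PyMT neutrophils had more UMIs per cell (medians 6514 and 16489.5 against 5368 and 5093) and a higher median mitochondrial share of UMIs (1.17% and 1.05% against 0.716% and 1.03%), so library quality stays open for these lists. Gclm, a subunit of the glutathione synthesis enzyme, was the 1 of 27 ferroptosis and antioxidant genes to rise (1.51, SE 0.30; 1 adjusted over the list alone; camera adjusted p = 0.153), and Ankrd37, a hypoxia-inducible gene, the 1 of 20 hypoxia genes (2.44, SE 0.48; 2 adjusted over the list alone). The hypoxia median was 0.12 (camera adjusted p = 0.0215, 0.072 with replicate blocks; adjusted p = 0.521 with an estimated correlation). Of 22 fatty acid and lipid genes 2 fell, Lpl, a lipoprotein lipase (-2.72, SE 0.44), and Scd1, a fatty acid desaturase with 0 UMIs in PyMT and 43 in wildtype (at least 17.1-fold lower). 3 fell adjusted over the list alone, the median was -0.01. The list test gave adjusted p = 0.32. In the primary granule and progenitor list Cd34, a progenitor surface protein, fell (-2.42, SE 0.44; 1.97 with mature clusters alone, adjusted p = 0.726), 0 of 11 rose, the median was 0.58. Camera gave adjusted p = 0.174 (0.0116 with replicate blocks). Markers of other cell types were lower in the same sums: monocyte and macrophage markers by a median of -1.53 (5 of 19 fell; camera adjusted p = 5.26e-16), stem and progenitor cell markers by -1.11 (adjusted p = 1.71e-07) and B cell markers by -2.35 (1 of 15 fell; adjusted p = 2.9e-09, or adjusted p = 0.104 with an estimated correlation). Adjusted p of the single genes in this paragraph ran from 0.00196 to 0.0355 (edgeR), each with 2 of 2 pairs in that direction. In all, 44 genes rose and 75 fell of 17401 tested (edgeR, 18 libraries), 409 passed with replicate blocks, 348 with DESeq2 and 73 with no doublets removed, and the count was 12 without wildtype replicate 1, 23 without PyMT replicate 1, 50 without wildtype replicate 2 and 47 without PyMT replicate 2. Of the 20 genes named for this comparison, 4, 9, 10 and 13 kept their call in those 4 fits.

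Marrow of mice given G-CSF and vehicle was compared to ask which of these changes the cytokine makes in mice without a tumor. Ifitm1 was 23.3-fold higher with G-CSF, at 1930 ± 962 CPM (n = 2) against 82.8 ± 4.52, Wfdc17 23.3-fold higher, at 1625 ± 799 against 69.7 ± 17.6, and Prok2 5.59-fold higher, at 120 ± 70.2 against 21.5 ± 0.680. These folds rest on TMM scaling. Without it Ifitm1 stood at 1156 and 2360 CPM with G-CSF (replicates 1 and 2) and 110 and 116 with vehicle. Wfdc17 then stood at 980 and 1980 against 105 and 83.1, and Prok2 at 65.2 and 153.5 against 28.2 and 30.5. Igfbp6 rose by 5.46 in log2 fold change (SE 0.69) and Stfa2, a stefin that inhibits cysteine proteases, by 4.65 (SE 0.95). Thbs1 fell by 4.93 on the log2 scale (SE 0.60), Fmnl2 changed by -2.499 (SE 0.33; its call held with mature clusters alone), and Sntb1 fell by 2.08 (SE 0.35) and St8sia1, a ganglioside sialyltransferase, by 1.86 (SE 0.31). Adjusted p ran from 0.00122 to 0.0449 (edgeR), each gene moving the same way in 2 of 2 pairs. Wfdc17, Ifitm1 and Prok2 were again the 3 of 31 immunosuppressive and protumour genes to rise. Adjusted over the list alone 4 rose and 1 fell, the median was 0.36. By camera, adjusted p was 0.000233, or adjusted p = 0.456 with an estimated correlation. Of 48 oxidative phosphorylation genes 48 were positive with TMM scaling and 32 by library totals, with medians of 0.67 and 0.09 where the medians of all genes were 0.00 and -0.57, and 0 passed alone (camera adjusted p = 5.49e-11, or adjusted p = 0.456 with an estimated correlation). In both pairs the G-CSF neutrophils also had a higher median mitochondrial share of UMIs (1.71% and 0.749% against 1.11% and 0.389%) and more UMIs per cell (medians 8245 and 9691 against 4870 and 6478), so library quality stays open. The G-CSF and STAT3 signalling list had 0 of 20 called and a median of 0.29 (camera adjusted p = 0.0286, 0.0985 by library totals; adjusted p = 0.456 with an estimated correlation). Lpl (-4.85, SE 0.48) and Scd1 (2 UMIs with G-CSF and 73 with vehicle, a ratio of 53.6 with a counting interval of 14.3 to 451) were the 2 of 22 fatty acid and lipid genes to fall. That list's median was 0.07, its mean -0.46 and its camera direction down (adjusted p = 0.455). 2 rose and 4 fell adjusted over the list alone. Ankrd37 was the 1 of 20 hypoxia genes to rise (2.47, SE 0.50; 1 adjusted over the list alone; median 0.28, 0.22 with such genes at their bound; camera adjusted p = 0.0313, 0.0835 with replicate blocks, 0.101 by library totals; adjusted p = 0.456 with an estimated correlation). Adjusted p of Lpl, Scd1 and Ankrd37 was 0.000177, 0.0331 and 0.041. Stem and progenitor cell markers were lower in the G-CSF sums (median -1.41, 0 of 10 passed; camera adjusted p = 1.01e-08), as were B cell markers (-2.37, 1 of 15 fell; adjusted p = 6.23e-10, or adjusted p = 0.0991 with an estimated correlation). Over all comparisons, the camera calls that held with an estimated correlation were monocyte and macrophage markers (adjusted p = 0.00587) and stem and progenitor markers (0.0142) in PyMT marrow and stem and progenitor markers with G-CSF (0.0131). With replicate blocks as well, these 3 gave adjusted p = 0.15, 0.294 and 0.151, so no camera call held under both. Of the 107 camera calls at the preset correlation 80 held by library totals, 27 did not, and 28 others were called. In all, 32 genes rose and 36 fell, 520 passed with replicate blocks, 523 with DESeq2 and 40 with no doublets removed, and 25 passed without G-CSF replicate 1 and 9 without vehicle replicate 2. The other G-CSF and vehicle libraries left out gave 71 and 97. Of the 12 genes named here, 7, 4, 6 and 9 kept their call in those fits.

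Fold changes with PyMT and with G-CSF, which share no library, had a Pearson correlation of 0.55 and a Spearman correlation of 0.57 across 17401 genes. Genes are not independent replicates, so no p is attached. Both comparisons came from the same fit with a shared spread per gene, so their calls are not independent either. The numbers for independent calls below are therefore not a chance level. Of the 44 genes higher with PyMT and 32 higher with G-CSF, 21 were shared, where independent calls would give 0.0809. Of the 75 and 36 lower genes 15 were shared, against 0.155, and 0 genes were called in opposite directions (10 of 30881 with no low-count filter, beside 85 higher and 204 lower in both). Wfdc17, Ifitm1, Prok2, Igfbp6, Thbs1, Sntb1 and Fmnl2 were among the shared genes. With replicate blocks 66 higher and 130 lower genes were shared, with mature clusters alone 41 and 24, with cells picked by markers 16 and 47, with unnamed clusters added 23 and 36, and with no doublets removed 14 and 8. Of the 15 shared lower genes 14 were tested with mature clusters alone, where 7 were called with PyMT and 12 with G-CSF, at medians of -2.79 and -3.57 (-2.42 and -2.77 over all stages). Shared higher genes numbered 3 without wildtype replicate 1, 10 without PyMT replicate 1, 12 without wildtype replicate 2, 11 without vehicle replicate 1, 2 without vehicle replicate 2 and 8 without G-CSF replicate 2. Shared lower genes numbered 3 without wildtype replicate 1, 2 without PyMT replicate 1, 8 without wildtype replicate 2, 3 without PyMT replicate 2, 5 without G-CSF replicate 1, 5 without vehicle replicate 2 and 8 without G-CSF replicate 2, and the correlation ran from 0.37 to 0.51 over the libraries left out. The G-CSF effect minus the PyMT effect had 0 genes past adjusted p 0.05 in edgeR, with 339 at an unadjusted p under 0.05, and 2 in DESeq2. EdgeR called 2 without PyMT replicate 1 and 9 without G-CSF replicate 2.

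**Figure D2:**
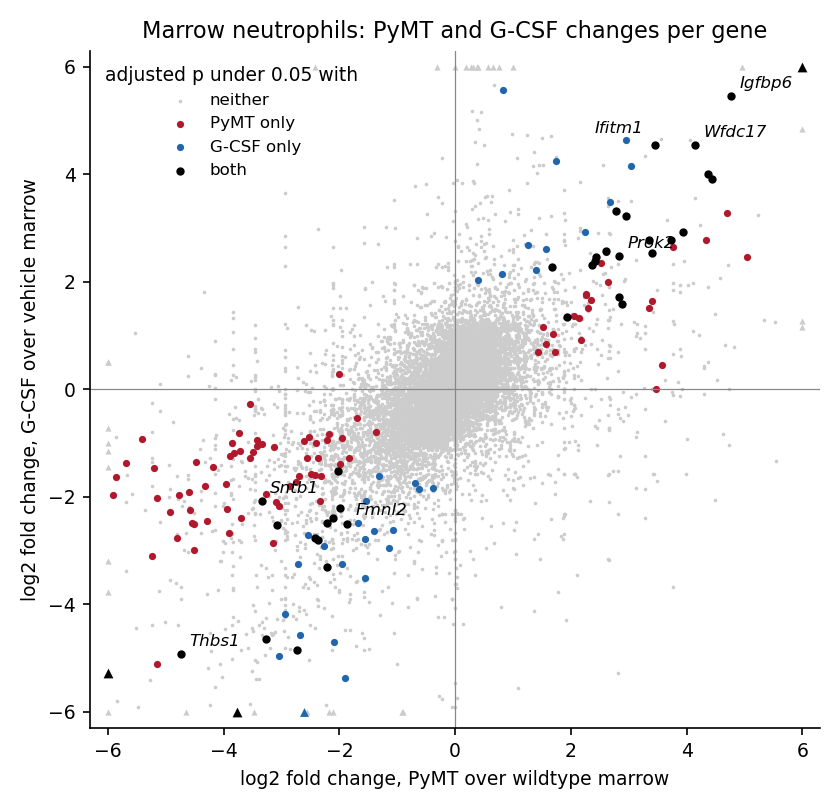
Log2 fold change of each of 17401 genes in marrow neutrophils with PyMT over wildtype (x axis) and with G-CSF over vehicle (y axis). Colour gives the comparison with an adjusted p under 0.05, and triangles are genes beyond the axis limits. The 21 genes higher in both and the 15 lower in both lie in the upper right and lower left, and the Pearson correlation is 0.55.

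Single marrow libraries asked the same of blocked G-CSF and of another tumor, with no replicate and so no test. In PyMT marrow neutrophils, Wfdc17 stood at 39.9 CPM (95% counting interval 37.8 to 42.0) with the antibody against G-CSF and 1542 CPM (1533 to 1551) with IgG, a log2 ratio of -5.11. Ifitm1 (-3.07), Steap4 (-2.90), Prok2 (-2.41), Stfa2 (-2.28), Upp1 (-1.88) and Npl (-1.66) were lower with the antibody, and Thbs1 (2.96), Sntb1 (1.74) and Fmnl2 (1.54) were higher. The median log2 ratio of the measured genes called higher with both PyMT and G-CSF was -1.15 with 0 of 20 positive, below each of 10000 random lists matched on expression (central 95% from 0.10 to 0.28), and that of the genes called lower with both was 1.32 with 12 of 12 positive. The G-CSF and STAT3 signalling list had a median of -0.08 (random lists 0.07 to 0.29) and the immunosuppressive and protumour list -0.09 (0.08 to 0.27). Markers of stem and progenitor cells (0.78) and erythroid cells (0.71) were higher in the antibody library. In E0771 marrow neutrophils Wfdc17 stood at 1184 CPM (1175 to 1192) against 112 CPM (108 to 115) in uninjected marrow, a log2 ratio of 3.35, with Steap4 (3.04), Igfbp6 (2.95), Ube2l6, a conjugating enzyme of ISG15 (2.82), Ifitm1 (2.49), Socs3 (1.89) and Il1b, a cytokine of inflammation (1.44), also higher. Scrg1 (-1.89), Cpa6 (-1.32), Foxp1 (-0.99) and Fmnl2 (-0.94) were lower. Cpa6 and Fmnl2 are among the 100 genes with the largest ratio of immature to mature neutrophils in wildtype marrow, so a shift in stage stays open for them. The genes called higher with both PyMT and G-CSF had a median of 1.08 with 21 of 21 positive (random lists -0.08 to 0.10). The G-CSF and STAT3 signalling (0.33), hypoxia (0.30), interferon response (0.36) and unfolded protein and amino acid stress (0.51) lists had medians above each of 10000 matched random lists, which do not keep the correlation between genes. B cell markers (-0.58) and monocyte and macrophage markers (-0.22) had medians below each of theirs.

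**Figure D3:**
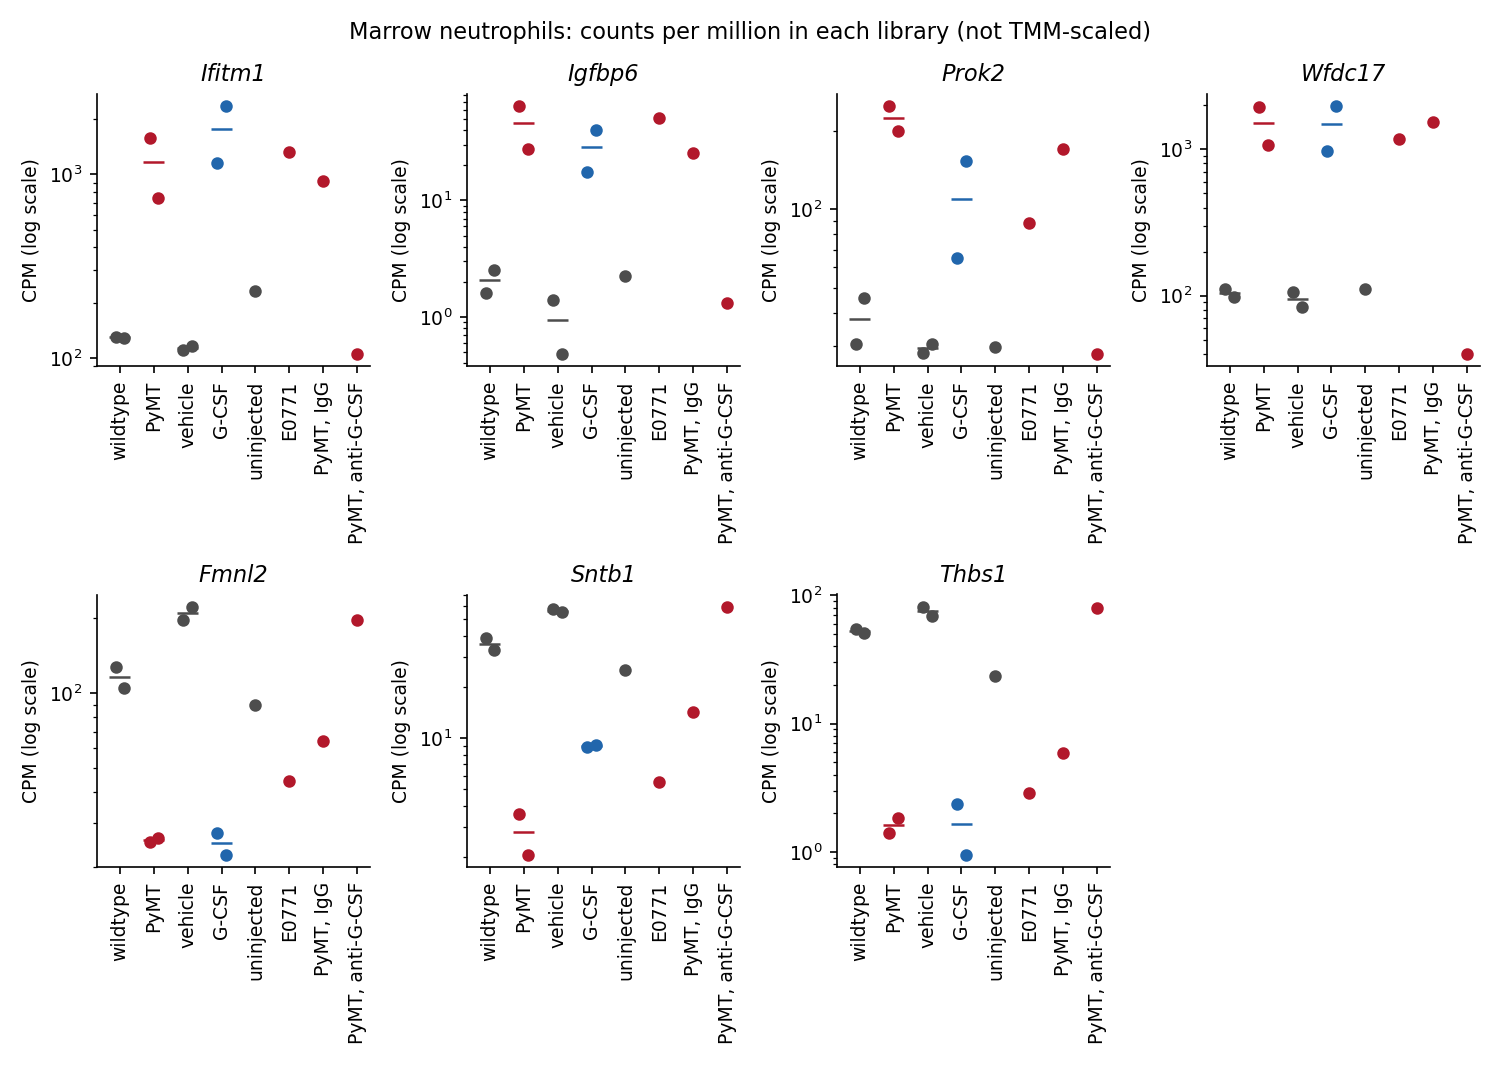
CPM in the neutrophil sums of the 12 marrow libraries (y axes, log scale) by group (x axes). The 7 genes are those that the fold change part of the naming rule took in the same direction with PyMT and with G-CSF. Genes named only as list members are left out. CPM here are not TMM-scaled, unlike group means in the text. Points are libraries and lines are means of groups with 2 libraries. Wfdc17 lies at 1542 CPM with IgG and 39.9 CPM with the antibody against G-CSF, both in PyMT marrow.

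Blood of PyMT and wildtype mice was compared to ask what circulating neutrophils carry. Prok2 was 75.3-fold higher in PyMT blood neutrophils (log2 6.24, SE 0.53), at 794 ± 214 CPM (n = 2) against 10.8 ± 2.71. Saa3, an acute-phase serum amyloid, had 30352 UMIs in PyMT and 2 in wildtype (ratio 1733, counting interval 480 to 14307), and Lipg had 2920 and 0 (at least 111-fold higher). Stfa3 (7.41, SE 1.25) and Stfa2 (6.09, SE 1.04) rose, as did Fam20c (2 UMIs in wildtype; ratio 67.6, interval 18.7 to 559). Cd80, a costimulatory ligand of T cells, fell by 3.50 (SE 0.38). Adjusted p of these genes ran from 2.75e-05 to 0.00394 (edgeR), each with 2 of 2 pairs in that direction. Among immunosuppressive and protumour genes 6 of 31 rose, with Wfdc17 at 20674 ± 4219 against 1537 ± 17.8 CPM and Ifitm1 at 13335 ± 4658 against 995 ± 62.3, 1 fell, and adjusted over the list alone 7 rose and 2 fell. The median was 0.56 (0.46 at the bound). The list test gave adjusted p = 0.000864, or adjusted p = 0.581 with an estimated correlation. Of 16 secondary granule genes, made in immature neutrophils, 4 rose, 0 fell, and 14 rose adjusted over the list alone: Serpinb1a, a serine protease inhibitor (3.09, SE 0.60), Cd177, a neutrophil surface glycoprotein (3.13, SE 0.62), Lcn2, a siderophore binder (2.91, SE 0.71), and Orm1, an acute-phase glycoprotein (2.66, SE 0.67; -0.72 with mature clusters alone, adjusted p = 0.787). That list's median was 2.86 (camera adjusted p = 2.89e-11, or adjusted p = 0.244 with an estimated correlation). With mature clusters alone its median was 0.55, with 0 of 16 called, though the rule that keeps those clusters reads granule genes. Kit, the stem cell factor receptor (3 UMIs in wildtype; ratio 59.3, interval 20.3 to 288), and Prtn3, proteinase 3 (3.50, SE 0.71), were the 2 of 11 primary granule and progenitor genes to rise (2 adjusted over the list alone; median 3.50, or 0.00 with genes at their bound; camera adjusted p = 0.364). The single genes of these lists had adjusted p from 0.000173 to 0.0375 (edgeR), each with 2 of 2 pairs in that direction.

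Further gene lists were read in the same PyMT blood neutrophils. Of 19 glycolysis genes 6 rose and 0 fell, among them Pfkl (2.52, SE 0.42), Tpi1 (2.47, SE 0.44), Ldha (2.03, SE 0.42) and Pgk1 (1.87, SE 0.29). 12 rose adjusted over the list alone, the median was 1.13. Camera gave adjusted p = 3.05e-10, or adjusted p = 0.172 with an estimated correlation. Of 20 hypoxia genes 8 rose and 1 fell (11 and 1 adjusted over the list alone), with Ankrd37 (3.03, SE 0.54), Mif, a macrophage migration inhibitory cytokine (2.399, SE 0.37), and Egln1, the oxygen-sensing prolyl hydroxylase (1.95, SE 0.27). The median was 1.22 (0.95 at the bound). By camera, adjusted p was 4.84e-07, or adjusted p = 0.172 with an estimated correlation. Of 48 oxidative phosphorylation genes 48 were positive, or 29 by library totals (medians 0.97 and 0.13 where the medians of all genes were 0.24 and -0.49; 2 rose, 20 adjusted over the list alone; camera adjusted p = 1.54e-11, or adjusted p = 0.581 with an estimated correlation). Il4ra, an interleukin 4 receptor chain (1.88, SE 0.32), and Socs3 (1.61, SE 0.39) were the 2 of 20 G-CSF and STAT3 signalling genes to rise (2 adjusted over the list alone; median 0.44; camera adjusted p = 0.0358, 0.0523 with replicate blocks, 0.7996 by library totals; adjusted p = 0.581 with an estimated correlation). In the interferon response list 2 of 33 rose, including Slfn4 (2.05, SE 0.38), and 5 adjusted over the list alone (median 1.02; camera adjusted p = 6.31e-05, or adjusted p = 0.581 with an estimated correlation). Gclm rose (1.96, SE 0.31) and Slc7a11, the cystine transporter, fell (-2.88, SE 0.61) among 27 ferroptosis and antioxidant genes, of which 2 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.64, 0.53 at the bound; camera adjusted p = 0.0423, 0.486 by library totals; adjusted p = 0.643 with an estimated correlation). Cxcr4, the marrow-retention chemokine receptor (-1.47, SE 0.36), and the integrin Itgax (-1.93, SE 0.35) were the 2 of 19 adhesion and migration genes to fall. 1 rose (the same counts adjusted over the list alone), the median was 0.15 and the mean -0.02 (camera down, adjusted p = 0.56). Lymphocyte genes were lower in the same sums: Bank1, a B cell scaffold protein (-3.13, SE 0.31), the T cell genes Bcl11b (-3.23, SE 0.76) and Skap1 (-2.94, SE 0.74), the B cell markers (median -2.51, 3 of 15 fell; camera adjusted p = 4.66e-10, or adjusted p = 0.172 with an estimated correlation) and the T cell markers (-2.43, 1 of 12 fell; adjusted p = 4.84e-07, or adjusted p = 0.244 with an estimated correlation). Single genes in this paragraph had adjusted p from 5.38e-05 to 0.0402 (edgeR), each with 2 of 2 pairs in that direction. In both pairs PyMT neutrophils had more UMIs per cell (medians 4134 and 4892 against 3396.5 and 3136), with a median mitochondrial share of 1.62% and 2.41% against 1.65% and 1.61%, so depth per cell stays open. In all 399 genes rose and 173 fell, and 1027 passed with replicate blocks, 1245 with DESeq2 and 1390 with no doublets removed. Scaling by relative log expression (RLE) moved the median of all genes from 0.24 to 0.00 and the split to 216 higher and 248 lower. The count was 201 without wildtype replicate 1, 991 without PyMT replicate 1, 244 without wildtype replicate 2 and 156 without PyMT replicate 2, with 19, 32, 19 and 19 of the 32 named genes keeping their call. A fit on the blood libraries alone called 296 genes, and 29 of the 32 kept their call.

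Lung of PyMT and wildtype mice was compared to ask the same of neutrophils in the tissue to which this tumor spreads. Prok2 was 232-fold higher in PyMT lung neutrophils (log2 7.86, SE 0.61), at 882 ± 193 CPM (n = 2) against 4.63 ± 2.60, and Saa3 had 72831 UMIs against 3 (ratio 2937, counting interval 1005 to 14240). The granule genes Ngp (7.45, SE 1.17), Camp, the cathelicidin (7.10, SE 1.64), and Ltf, lactoferrin (5.61, SE 1.14; -0.68 with mature clusters alone, adjusted p = 0.822), rose, Ngp from 58.0 ± 62.0 to 10649 ± 7150 CPM. Stfa3 (7.23, SE 1.32), Lipg (6.37, SE 1.09), Lbp, which binds lipopolysaccharide (5.47, SE 0.59; one of the 100 genes of immature marrow neutrophils, its call held with mature clusters alone), and Stfa2 (5.42, SE 1.02) rose too. Adjusted p of these genes ran from 4.72e-06 to 0.02 (edgeR), each with 2 of 2 pairs in that direction. Of 16 secondary granule genes 10 rose, 0 fell, and 15 rose adjusted over the list alone, with Orm1 (1 UMI in wildtype; ratio 225, interval 40.3 to 8877), Serpinb1a (4.51, SE 0.67) and Lcn2 (4.34, SE 0.76). The median was 3.96 (3.38 at the bound). The list test gave adjusted p = 9.03e-20, or adjusted p = 0.0943 with an estimated correlation. With mature clusters alone the median of this list was 1.45, with 1 of 16 called, though the rule that keeps those clusters reads granule genes. Glycolysis had 8 of 19 genes higher and 0 lower (14 adjusted over the list alone), with Ldha (2.59, SE 0.43), Tpi1 (2.42, SE 0.45), Pgk1 (1.89, SE 0.29) and the glucose transporter Slc2a1 (1.67, SE 0.31), a median of 1.34 and camera adjusted p = 1e-11, or adjusted p = 0.0843 with an estimated correlation. Hypoxia had 7 of 20 higher and 0 lower (13 and 1 adjusted over the list alone), with Ankrd37 (3.37, SE 0.56), Mif (2.96, SE 0.39) and P4ha1, a prolyl hydroxylase of collagen (2.47, SE 0.42), a median of 1.21 and camera adjusted p = 2.3e-09, or adjusted p = 0.0843 with an estimated correlation. Of 31 immunosuppressive and protumour genes 7 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.52), with Wfdc17 (3.66, SE 0.53) and Ifitm1 (3.85, SE 0.58). Camera gave adjusted p = 1.17e-05, or adjusted p = 0.406 with an estimated correlation. The single genes of these lists had adjusted p from 0.000619 to 0.00659 (edgeR), each with 2 of 2 pairs in that direction.

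Other gene groups in PyMT lung neutrophils were mixed. Gclm (3.46, SE 0.35) and Hmox1, the haem oxygenase (1.68, SE 0.38), were the 2 of 27 ferroptosis and antioxidant genes to rise (2 adjusted over the list alone; median 0.41; camera adjusted p = 0.0322, 0.0767 with replicate blocks, 0.409 by library totals; adjusted p = 0.674 with an estimated correlation). Bcl2l1, which encodes the survival factor BCL-XL, rose (2.18, SE 0.42), and the survival genes Bcl2 (-3.89, SE 0.90) and Bcl2a1d (-3.24, SE 0.58) fell, the 3 of 18 apoptosis regulation genes called (1 higher and 3 lower adjusted over the list alone; median 0.06, mean -0.24; camera down, adjusted p = 0.802). Markers of NK and T cells fell in the same sums, so RNA of such cells stays open as a source of the fall of Bcl2 and Bcl2a1d. The lipid carrier Fabp5 (1.98, SE 0.41) and the cholesterol exporter Abca1 (3.47, SE 0.70) were among 3 of 22 fatty acid and lipid genes that rose. 1 fell, 5 rose and 3 fell adjusted over the list alone, and the median was 0.06 (camera adjusted p = 0.52). Kit rose (4.05, SE 0.56) and Nkg7, a granule protein of cytotoxic cells, fell (-4.48, SE 0.51) in the primary granule and progenitor list, where 2 of 11 rose and 1 fell (5 and 1 adjusted over the list alone; median 2.98, 0.60 at the bound; camera adjusted p = 0.35). Cell cycle genes had a median of -1.22, with 1 of 30 higher and 3 lower (1 and 10 adjusted over the list alone; camera adjusted p = 1.97e-05, or adjusted p = 0.579 with an estimated correlation). Genes of other cells were lower in the same sums: Bank1 (-3.92, SE 0.32), the lymphocyte chemokine Ccl5 (-4.25, SE 1.17), Cldn18, a claudin of alveolar epithelium (-3.24, SE 0.85), the NK cell markers (median -4.29, 6 of 9 fell; camera adjusted p = 2.66e-11, or adjusted p = 0.0843 with an estimated correlation) and the T cell markers (-3.62, 3 of 12 fell; adjusted p = 1.11e-08, or adjusted p = 0.119 with an estimated correlation). Single genes in this paragraph had adjusted p from 5.77e-06 to 0.0461 (edgeR), each with 2 of 2 pairs in that direction. In both pairs PyMT neutrophils had a higher median mitochondrial share of UMIs (0.711% and 2.54% against 0.552% and 1.73%) and more UMIs per cell (medians 3718 and 4373.5 against 2925.5 and 3141.5), so library quality stays open in lung. In all 454 genes rose and 392 fell, against 3661 in total with no doublets removed and 1893 with DESeq2. RLE moved the median of all genes from 0.09 to -0.16 and the split to 306 higher and 630 lower. The count was 102 without wildtype replicate 2 and 239 without PyMT replicate 3, and 12 and 25 of the 33 named genes then kept their call, against 28 without wildtype replicate 3 and 32 without PyMT replicate 2. A fit on the lung libraries alone called 58 genes, and 16 of the 33 kept their call.

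The PyMT effect in blood and in lung was set against that in marrow by a test of the difference. In blood 6 genes differed from marrow, all higher (edgeR): Kit by 6.14 in log2 (SE 0.77, adjusted p = 0.00933), Tceal9 by 4.89 (SE 0.66, adjusted p = 0.0111), Thbs1 by 4.84 (SE 0.79, adjusted p = 0.0477) and Cnnm2, a membrane protein of magnesium transport, by 4.18 (SE 0.62, adjusted p = 0.0203) among them. Thbs1 was at 34.1 ± 15.6 CPM in PyMT and 32.4 ± 16.5 in wildtype blood, beside its fall in marrow. In lung 12 genes were higher and 4 lower than in marrow, with Prok2 at 5.02 (SE 0.70, adjusted p = 0.0123), Orm1 at 7.93 (SE 1.39, adjusted p = 0.0387), Lbp at 4.22 (1.46 with mature clusters alone, adjusted p = 1), Ly6g, a neutrophil surface marker, at 3.96 and Kit at 4.37, and with Nkg7 at -5.43 (SE 0.65, adjusted p = 0.00239) and Bank1 at -2.55. Each of these genes had the same sign in 4 of 4 differences between a marrow pair and a pair of the other tissue. Nkg7 is a gene of cytotoxic cells, at 42.3 ± 4.20 CPM in wildtype lung and 1.88 ± 0.0139 with PyMT, and Bank1 one of B cells. Markers of NK and T cells also fell in the lung sums, so RNA of lymphocytes in the wildtype lung sums stays open for both. Scaling by RLE moved the median of all genes from 0.31 to 0.05 for blood and from 0.19 to -0.07 for lung, where it called 11 higher and 8 lower. Replicate blocks gave 49 and 68 genes. The blood count (6) was 2 without marrow wildtype replicate 1, 3 without marrow wildtype replicate 2, 1 without marrow PyMT replicate 2, 2 without blood wildtype replicate 1, 1 without blood wildtype replicate 2 and 28 without blood PyMT replicate 1. The lung count (16) was 4 without marrow wildtype replicate 1, 9 without marrow PyMT replicate 1, 2 without marrow wildtype replicate 2, 1 without marrow PyMT replicate 2, 1 without lung wildtype replicate 2, 48 without lung wildtype replicate 3 and 5 without lung PyMT replicate 3. Of the 4 genes named for blood, 0 (without blood wildtype replicate 2) to 4 kept their call, and of the 7 named for lung, 1 (without marrow wildtype replicate 2, marrow PyMT replicate 2 or lung wildtype replicate 2) to 7. With mature clusters alone 0 genes passed for blood and 2 for lung, and 0 of the 4 and 1 of the 7 named genes kept their call. For lung minus blood edgeR called 0 genes, with 659 at an unadjusted p under 0.05, and DESeq2 called 7.

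**Figure D4:**
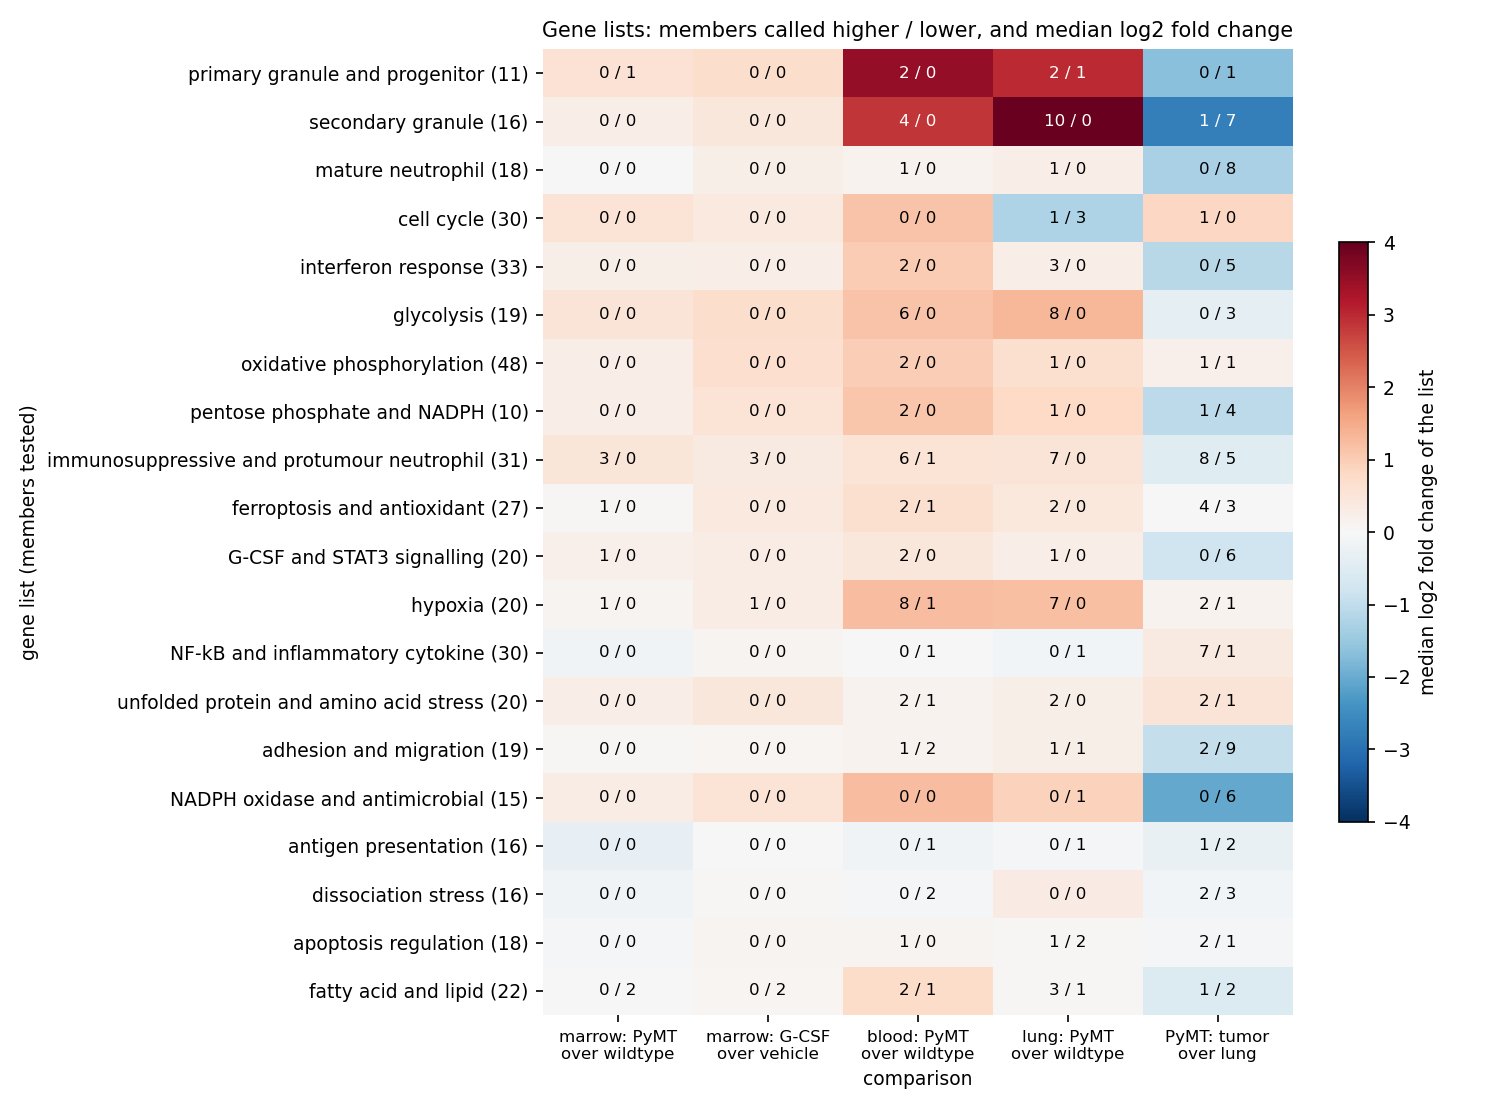
Median log2 fold change (colour) of 20 gene lists fixed beforehand (y axis, members tested) in 5 comparisons of neutrophils (x axis), with the number of members called higher and lower in each cell. Secondary granule genes run from a median of 0.27 in PyMT marrow to 2.86 in blood and 3.96 in lung, and -2.73 in tumor over lung.

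Spleen and the lung library titled Mets had no replicate and no test. In PyMT spleen neutrophils the primary granule genes Elane (215 CPM, 95% counting interval 200 to 231), Mpo (103, 92.5 to 114) and Ctsg (85.3, 76.0 to 95.5) were measured where wildtype spleen had 0 UMIs of 353263, for which the 95% counting interval reaches 10.4 CPM. Prtn3 stood at 214 CPM (199 to 229) against 1 UMI in wildtype and Prok2 at 130 CPM (118 to 142) against 2 UMIs. The primary granule and progenitor list had a median log2 ratio of 2.89 (8 of 10 positive; random lists -0.62 to 0.22), the secondary granule list 1.31 (14 of 16; -0.56 to 0.02) and the cell cycle list 1.203 (29 of 30; -0.33 to 0.18). Cd80 (-2.76) and Ptpn22, a phosphatase of lymphocyte signalling (-2.84), were lower. Erythroid markers were higher in the same sums, with a median of 1.60. In the library titled Mets, neutrophils differed little from those of PyMT lung replicate 3 of the same batch: Ubb, which encodes ubiquitin, had a log2 ratio of 0.79 and Eno1, a glycolytic enolase, 0.47, and Zfp36, which destabilises cytokine transcripts (-1.05), Ccl4 (-0.99), Osm (-0.68) and Ptgs2, the inducible cyclooxygenase (-0.68), were lower. The dissociation stress list had a median of -0.15 (2 of 16 positive; random lists -0.03 to 0.09) beside 0.26 for epithelial markers (6 of 7 positive).

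Tumor and lung neutrophils of PyMT mice were compared to ask what differs at the primary site. Spp1, osteopontin, was 12.1-fold higher in tumor neutrophils (log2 3.60, SE 0.47), at 274 ± 130 CPM (n = 2) against 22.7 ± 15.3. Il10, a suppressive cytokine, rose by 5.24 (SE 1.00), at 59.8 ± 68.4 CPM against 1.49 ± 1.39 (2.91 without tumor replicate 2, adjusted p = 0.16; 1.17 with cells picked by markers, adjusted p = 0.212), and Arg1, arginase 1, had 15 UMIs in tumor and 3 in lung (ratio 127, counting interval 35.9 to 685). Hpgd, which breaks down prostaglandins, had 0 UMIs in tumor and 840 in lung (at least 11.0-fold lower), and Chil5, a chitinase-like protein, 1 against 934 (ratio 36.8, interval 6.58 to 1453). Genes of epithelium rose in the same sums, Fxyd3 by 9.37 (SE 0.91), Igfbp5 by 7.80 (SE 1.05), Ehf by 7.70 (SE 1.05) and Egfr by 6.83 (SE 1.47). Of 14 epithelial markers 8 rose and 3 fell (9 and 4 adjusted over the list alone; median 3.88, mean -0.51; camera up, adjusted p = 1.17e-05, or adjusted p = 0.406 with an estimated correlation). Tumor neutrophils had a median mitochondrial share of 1.76% and 4.37% of UMIs, against 0.711% and 2.54% in lung of the same batches, so a difference in RNA quality stays open. These sums hold 163 and 181 cells, with 29 and 49 UMIs of the PyMT transgene. Ms4a6d, a gene of macrophages (5.15, SE 0.80; -1.654 with cells picked by markers one by one), and H2-Eb1, an MHC class II chain (3.06, SE 0.72; -1.979 with that choice), rose too. Of 19 monocyte and macrophage markers 6 rose and 2 fell (6 and 3 adjusted over the list alone; median 0.10, mean -0.32; camera up, adjusted p = 0.195). How much RNA of epithelium or macrophages these sums hold was not estimated, so the source of Spp1, Il10 and Arg1 stays open. Adjusted p of these genes ran from 0.000531 to 0.0226 (edgeR), each with 2 of 2 pairs in that direction. Among immunosuppressive and protumour genes 8 of 31 rose and 5 fell (10 and 8 adjusted over the list alone; median -0.49, or -0.43 at the bound, mean 0.12; camera up, adjusted p = 0.973). Of 30 NF-kB and inflammatory cytokine genes 7 rose and 1 fell (9 and 2 adjusted over the list alone): the survival genes Bcl2a1d (4.09, SE 0.60; -3.114 with cells picked by markers) and Bcl2a1b (2.75, SE 0.63; -2.998) and the adhesion ligand Icam1 (2.68, SE 0.58; -2.79) rose and Zfp36 (-3.12, SE 0.40) fell. The median was 0.35. By camera, adjusted p was 0.0762 (0.022 with replicate blocks). In the hypoxia list Vegfa, an angiogenic factor (1.55, SE 0.45; -1.385 with cells picked by markers), and Mif (1.18, SE 0.35) were the 2 of 20 to rise. 1 fell (3 and 1 adjusted over the list alone; median 0.13; camera adjusted p = 0.38). Tfrc, the transferrin receptor (2.64, SE 0.51), and Prdx1, a peroxiredoxin (2.05, SE 0.41), were among 4 of 27 ferroptosis and antioxidant genes that rose, and Gclm (-1.67, SE 0.32) among 3 that fell (the same counts adjusted over the list alone; median -0.02, mean 0.15; camera up, adjusted p = 0.973). The single genes of these lists had adjusted p from 0.000505 to 0.0371 (edgeR), again with 2 of 2 pairs in that direction.

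Lists of granule, mature and signalling genes were read in the same tumor and lung sums. Of 16 secondary granule genes 7 fell, among them Ngp (-3.34, SE 0.96; 0.49 with mature clusters alone, adjusted p = 0.7975), Orm1 (-3.21, SE 0.82), Serpinb1a (-2.99, SE 0.63), Cd177 (-2.66, SE 0.63) and the collagenase Mmp8 (-2.51, SE 0.47). The 1 that rose was Ltc4s, the leukotriene C4 synthase (3.98, SE 0.65; -3.986 with cells picked by markers). Adjusted over the list alone 13 fell and 1 rose, the median was -2.73 (-2.58 at the bound). The list test gave adjusted p = 3.01e-08, or adjusted p = 0.406 with an estimated correlation. Of 18 mature neutrophil genes 8 fell and 0 rose (13 and 1 adjusted over the list alone), with the chemoattractant receptor Fpr1 (-1.86, SE 0.34), the selectin ligand Selplg (-1.40, SE 0.35) and the chemokine Ccl6 (-1.68, SE 0.43). The median was -1.29. Camera gave adjusted p = 1.95e-06, or adjusted p = 0.453 with an estimated correlation. Of 20 G-CSF and STAT3 signalling genes 6 fell and 0 rose (8 adjusted over the list alone), with Stat3 (-1.48, SE 0.32), Osm, a cytokine of the interleukin 6 family (-2.71, SE 0.63), and the transcription factor Cebpd (-1.80, SE 0.38), at a median of -0.81 (camera adjusted p = 8.62e-05, or adjusted p = 0.406 with an estimated correlation). Of 33 interferon response genes 5 fell and 0 rose (10 adjusted over the list alone), with Slfn1 (-1.74, SE 0.36) and Oasl2 (-1.69, SE 0.46), at a median of -1.12 (-0.95 at the bound; camera adjusted p = 0.000233, or adjusted p = 0.614 with an estimated correlation). NADPH oxidase and antimicrobial genes included Cybb, the catalytic oxidase subunit (-2.81, SE 0.71; 0.17 with mature clusters alone, adjusted p = 0.892), and the lysozyme Lyz2 (-2.45, SE 0.69). 6 of 15 fell and 0 rose (9 and 1 adjusted over the list alone; median -2.04, -1.17 at the bound; camera adjusted p = 1.77e-05, or adjusted p = 0.406 with an estimated correlation). The pentose phosphate enzymes G6pdx (-2.32, SE 0.42) and Tkt (-1.97, SE 0.53) were among 4 of 10 that fell, with 1 that rose (5 and 1 adjusted over the list alone; median -1.05; camera adjusted p = 0.00451, or adjusted p = 0.614 with an estimated correlation). Of 19 adhesion and migration genes 9 fell, with the integrin Itga4 (-1.94, SE 0.35), and 2 rose (11 and 2 adjusted over the list alone; median -0.96; camera adjusted p = 8.62e-05, 0.136 by library totals; adjusted p = 0.406 with an estimated correlation). Fos (-2.49, SE 0.57) and Dusp1 (-2.62, SE 0.58), early response genes, fell among 16 dissociation stress genes, of which 3 fell and 2 rose (5 and 2 adjusted over the list alone; median -0.12; camera adjusted p = 0.216). Single genes in this paragraph had adjusted p from 0.00176 to 0.0338 (edgeR), each with 2 of 2 pairs in that direction. In all 1127 genes rose and 926 fell, 2053 together, against 12302 with cells picked by markers and 5506 with no doublets removed. RLE moved the median of all genes from -0.18 to -0.02 and the split to 1310 higher and 669 lower. The count was 1131 without lung replicate 2, 856 without tumor replicate 1 and 994 without tumor replicate 2, and 34, 18 and 29 of the 41 named genes then kept their call, against 34 without lung replicate 3. A fit on the tumor and lung libraries alone called 676 genes, and 34 of the 41 kept their call. Picking cells by markers one by one took 773 and 1076 of 5813 and 7072 kept tumor cells, where clusters gave 163 and 181. It turned the direction of 7 of the 41, each past the threshold (edgeR, adjusted p from 2.1e-05 to 0.0498).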

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

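The tests with cells picked one by one by markers, the test without PyMT marrow replicate 2, the free-RNA values of markers and the values of shared lower marrow genes with mature clusters alone were chosen after the results they measure were seen. The test of immature marrow genes was added after the result with mature clusters was seen, though before its own value. At the same step a fall with mature clusters was ruled unable to decide, because of how those clusters are kept; by the bound first written it would have counted for immature neutrophils.

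Differences in the PyMT effect between tissues, or between G-CSF and PyMT in marrow, drew attention in 6 genes for blood minus marrow and 16 for lung minus marrow. Medians of gene lists differed for blood minus marrow by 2.51 (secondary granule), 0.75 (interferon response), 0.69 (glycolysis), 0.69 (oxidative phosphorylation), 0.61 (hypoxia) and 0.56 (fatty acid and lipid; adjusted p = 0.0428, 0.0545 with replicate blocks, 0.0588 by library totals). For lung minus marrow they differed by 3.40 (secondary granule), -1.74 (cell cycle), 0.80 (glycolysis), 0.38 (oxidative phosphorylation; adjusted p = 0.525 by library totals), 0.80 (hypoxia) and 0.41 (dissociation stress). For lung minus blood they differed by 0.66 (secondary granule), -2.11 (cell cycle) and 0.56 (dissociation stress), and for G-CSF minus PyMT in marrow by 0.40 (oxidative phosphorylation). Each of these lists passed camera with the preset correlation and none with an estimated correlation, where the lowest adjusted p was 0.16 (secondary granule, cell cycle and hypoxia, lung minus marrow). Medians of these differences were not set at a bound for genes with a group at 0. The cell cycle genes Aurkb, Mcm5 and Bub1 had 0 UMIs in wildtype blood, so the size of -2.11 for lung minus blood is uncertain. UMIs of the Cre transgene, which no comparison used, were found in 16 libraries, up to 1100 in a library, and 0 in the 2 libraries of genotype Naive; 7 of 23 libraries labelled with the Cre genotype had 0 (both marrow replicate 2 libraries of PyMT and wildtype, 4 blood libraries, and wildtype lung replicate 3, against 176 in its PyMT pair).

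In PyMT blood 173 genes and in PyMT lung 392 genes were lower in neutrophil sums, among them lymphocyte genes such as Bank1. RNA released by other cells was weighed by the level it would give in the wildtype sums. At or under 2 times that level in both wildtype libraries sat 16.77% (95% interval 11.4 to 23.3) of 167 lower genes in blood. In lung 15.47% (12.0 to 19.5) of 375 did. Of all tested genes 22.63% in blood and 21.3% in lung did. Of the other-cell markers that set this level 56.7% (43.2 to 69.4) and 57.8% (46.9 to 68.1) did. The lower genes sat there less often than the markers, but the markers themselves miss the 75% asked of free RNA. The test therefore cannot decide whether released RNA is the cause. Taken alone, 32.34% and 17.37% of lower genes did so in the wildtype blood libraries (41.78% and 28.84% of all tested genes). In wildtype lung replicates 2 and 3 it was 20.8% and 49.6% (26.1% and 45.76%). Released RNA stays open for these genes. With cells picked one by one by markers, 18.62% of the lung genes kept their call and their median moved from -2.61 to -1.18 (median SE 0.58 and 0.45; 361 of 392 stayed below 0), and with no doublets removed 2240 genes were lower, so cells of another type within the wildtype sums are a candidate explanation in lung. In blood 54.34% kept their call and the median moved from -2.56 to -2.04 (median SE 0.51 and 0.52; 173 of 173 stayed below 0), between the bounds set, so that explanation cannot be told apart there from a change in neutrophils.

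Secondary granule genes were higher in PyMT blood (median 2.86) and lung (3.96). With mature clusters alone the median was 0.5548 in blood, with 0 of 16 called, and 1.453 in lung, with 1 of 16, but the rule that keeps those clusters reads granule genes, so immature neutrophils in the sums cannot be told apart from a change within mature cells. Genes of immature marrow neutrophils outside every list had a median of 0.4779 in blood (5 of 100 higher, 2 lower) and -0.568 in lung (6 higher, 9 lower). Other dividing cells in the wildtype sums would lower these medians too. Mki67 stood at 17.8 ± 17.8 CPM in wildtype lung sums and 5.54 ± 0.806 with PyMT, so the lung value cannot decide. In wildtype blood sums, markers of other cells stood at a median of 16.68% and 2.763% of their level in other cells. With PyMT it was 5.185% and 0.5461%. RNA of other cells may therefore lower the blood value too, and it cannot decide either. Many of the 100 immature marrow genes belong to dividing cells, so a later stage stays open. Granule RNA released from immature cells also stays open: in the PyMT library nearer to it, mature neutrophils exceeded T-like cells by a median log2 ratio of 0.9112 in blood (2.34 in the other) and 1.499 in lung (1.90).

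In marrow 21 genes, Wfdc17 and Ifitm1 among them, were higher with both PyMT and G-CSF. A change in the part of immature cells was argued against as the whole cause. With mature clusters alone the median of these genes was 3.49 with PyMT and 2.419 with G-CSF (2.96 and 2.78 over all stages), with 19 and 14 of 21 called. The genes were called in sums that hold these same mature cells, and stage may still differ within mature clusters. A shift in late maturation therefore stays open for these genes. PyMT marrow replicate 2, with 1121 cells, was argued against as the source, since their median without it was 3.401. G-CSF acting in tumor-bearing mice is a candidate explanation: their median ratio between the antibody and IgG libraries lay at percentile 0 of matched random lists, in 1 library each. Those libraries also differed in UMIs per neutrophil (median 10548 with IgG, 5264 with the antibody) and mitochondrial share (0.557% and 0.378%), so library quality stays open.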

How the results depend on the processing

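Unnamed clusters with a neutrophil best score, the tumor libraries exchanged between blocks, share pairs of a batch flipped together and library totals for gene lists were alternatives chosen after seeing the data; the cause of each change below was not tested, except that fits without a filter test more genes and fits with a library left out hold fewer. Genes past the threshold (119 PyMT marrow, 572 blood, 846 lung, 68 G-CSF, 2053 tumor over lung, 6 blood minus marrow, 16 lung minus marrow, 0 lung minus blood, 0 G-CSF minus PyMT) changed as follows. With DESeq2 they were 348, 1245, 1893, 523, 85, 372, 7 and 2 (tumor within 1.5 times). With no filter they were 578, 996, 1375, 740, 139, 259, 50 and 80 (tumor within). With the replicate block they were 409 in PyMT marrow, 1027 in blood, 520 with G-CSF, 49, 68, 1 and 1 for the differences. With the tumor libraries exchanged between blocks 2732 genes passed in tumor over lung. With only the libraries of the comparison they were 371, 296, 58, 1406, 676 and 3 for blood minus marrow. With no doublets removed they were 73, 1390, 3661, 40, 5506 and 301 for lung minus marrow. With cells picked by markers they were 366 with G-CSF, 12302 in tumor over lung, 218 for lung minus marrow and 4 for lung minus blood. With mature clusters alone they were 180 in PyMT marrow, 527 in lung, 155 with G-CSF, 0 for blood minus marrow and 2 for lung minus marrow. With the unnamed clusters added they were 170 with G-CSF. The fold change correlation of PyMT and G-CSF was 0.29 with no filter, 0.47 with cells picked by markers and 0.40 with mature clusters alone. The share difference was 29.4 points in marrow and 49.3 in lung with cells picked by markers and 43.4 in lung with no doublets removed. Of 107 gene list calls 3 held with an estimated correlation and 80 by library totals.

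With mature clusters alone Cd34 was at 1.97 in PyMT marrow, Orm1 at -0.72 in blood, Ltf at -0.68 in lung, and Ngp at 0.49 and Cybb at 0.17 in tumor over lung. With cells picked by markers Icam1 was at -2.79, Bcl2a1b at -2.998, Bcl2a1d at -3.114, Vegfa at -1.385, Ltc4s at -3.986, Ms4a6d at -1.654 and H2-Eb1 at -1.979 in tumor over lung. With 1 library left out the counts ran from 12 to 50 in PyMT marrow, 156 to 991 in blood, 102 to 924 in lung, 9 to 97 with G-CSF, 856 to 1756 in tumor over lung, 1 to 28 for blood minus marrow, 1 to 48 for lung minus marrow, 0 to 0 for lung minus blood and 0 to 9 for G-CSF minus PyMT; the correlation ran from 0.37 to 0.51. Share differences ran from 28.5 to 35.0 points over tissues, 23.02 to 27.95 in marrow, 22.9 to 45.9 in blood, 43.5 to 46.9 in lung and 21.5 to 28.9 with G-CSF. Of 149 named gene values 148 kept their call with DESeq2, 144 with RLE scaling, 149 with the replicate block, 149 with no filter, 148 with at least 1000 UMIs, 143 with the unnamed clusters added, 131 with no doublets removed, 120 with only the libraries of the comparison, 114 with mature clusters alone (30 weaker, 5 reversed) and 113 with cells picked by markers (29 weaker, 7 reversed). With 1 library left out 404 values kept their call and 236 were weaker. Neutrophil sums in tumor were 543074 and 505558 UMIs.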

Other observations

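No test in this part was chosen after its result was seen. B cells were rare in marrow with a tumor or G-CSF: 0.632% ± 0.893 of cells (SD, n = 2) with PyMT against 18.8% ± 2.65 in wildtype, 0.232% ± 0.329 with G-CSF against 10.2% ± 1.41 with vehicle, and 1.61% with E0771 against 17.6% in uninjected marrow. PyMT marrow held 2.83% B cells with IgG and 7.34% with the antibody against G-CSF. Erythroid cells were 2.59% ± 1.38 with PyMT and 7.65% ± 0.103 in wildtype marrow, and 2.68% with IgG and 13.8% with the antibody. Blood T cells were 26.5% ± 0.575 with PyMT and 42.8% ± 8.75 in wildtype, and lung T cells 6.86% and 7.33% with PyMT and 27.7% and 18.4% in wildtype. Spleen erythroid cells were 4.95% with PyMT and 0.348% in wildtype. These shares add up to a whole, so a larger neutrophil share lowers the others, and no test was made.

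The PyMT transgene had 70 UMIs in the lung library titled Mets, 52 of them in cells named epithelial, against 9 and 9 UMIs in the other PyMT lung libraries. The E0771 and uninjected marrow libraries had 3 and 10 UMIs, against 4 and 2 in PyMT marrow replicates 1 and 2.

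The genes called higher with G-CSF may mark a G-CSF programme in other mice. In E0771 against uninjected marrow their median log2 ratio was 1.03, at percentile 100 of 10000 matched random lists, with 27 of 28 positive. In PyMT against wildtype spleen it was 1.38, also at percentile 100, with 23 of 27 positive; with 1 library per group other differences between these mice stay open.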
